A study of Homo sapiens with 13 samples.

How the data were processed

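RNA from human neural organoids of the line NIBSC8 was measured in 13 libraries made, per the labels, with the TruSeq Stranded mRNA kit. The deposited table holds counts, whole numbers per Ensembl gene ID and library with no normalization. Per the submitters' processing notes the tools were Trim Galore 0.6.7, cutadapt 5.0, STAR 2.7.10a, Salmon 1.10.1 and featureCounts from Subread 2.0.1, with the genome build GRCh38. Which tool made the counts, the strand setting and the annotation release are not given in the sources used here. The table has 63241 gene IDs, of which 62666 were matched by ID to symbols and 575 were not, and 36257 had a count in any library. Gene positions were taken by ID from GENCODE 29 on GRCh38. Total counts per library ran from 22630769 to 33257893. Genes that share exons or have close copies, such as clustered protocadherins, ribosomal protein genes with pseudogenes and mitochondrial genes with nuclear copies, take reads in a way that the counting settings decide.

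Libraries were grouped by the week and batch in their labels: 3 of week 8 in batch 1, 3 of week 8 and 3 of week 12 in batch 2, and 4 of week 13 in batch 3. A single edgeR 4.0.16 quasi-likelihood model in R 4.3.3 with 4 group means, trimmed-mean (TMM) normalization and the filterByExpr filter was fitted to all 13 libraries, which left 19377 genes tested, 9 residual degrees of freedom and a common biological coefficient of variation of 0.172. Contrasts were tested by the quasi-likelihood F test (two-sided) with Benjamini-Hochberg adjustment at 0.05. The 4 contrasts were week 12 against week 8 in batch 2, week 13 against the unweighted mean of the week 8 batches, week 13 against week 12, and week 8 of batch 2 against batch 1. A further contrast, week 13 of batch 3 against week 8 of batch 1, shares no library with the first, and the overlap of both was set beside the number expected of independent lists. CPM used TMM-scaled totals, and log2 CPM used a prior count of 2. No fold change is given against a group in which every library had 0 counts.

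The comparisons, 39 gene lists, the panel of 20 genes, the rule for named genes and the alternatives were chosen before the data were examined, except where the text says otherwise. Lists with at least 3 measured members, 37 of 39, were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation between genes of 0.01, adjusted over the lists, beside camera with an estimated correlation and fry. With the estimated correlation no list passed in any of the 4 contrasts, where 3, 1, 2 and 4 of 37 lists had an unadjusted p under 0.05, and fry called 19, 12, 25 and 14 lists in the order above. The fixed rule named, for week 12 against week 8, the 8 higher and 8 lower genes with the largest absolute log2 fold change among those with adjusted p under 0.05, a mean of at least 5 CPM over the libraries compared and no overlap between the groups, and 5 and 5 for the other contrasts. Symbols of clones, LOC, LINC and antisense genes were passed over. For each list up to 4 members with the smallest adjusted p and the most highly expressed member that did not pass were also named in the first 2 contrasts, and the panel in all. Some list members and 1 panel gene are not reported here.

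The procedure was tested on simulated data, with a 1.5-fold change added to 100 genes and a 2-fold change to 100 others. For week 12 against week 8 it recovered 81 genes of a 2-fold change and 27 of a 1.5-fold change, for week 13 against week 8 88 and 47, for week 13 against week 12 81 and 30, and for the week 8 batches 76 and 36. Among the genes of the same simulations that had no change added, 7, 8, 5 and 5 were called. These fits held 18962, 18961, 19003 and 18952 genes, the changed ones included. A list given a shift was called in all 4, with none of 38 unchanged lists called by camera with either correlation or by fry. Simulated genes varied independently, with the same spread in every group, and the lists were drawn at random. The simulation therefore cannot tell how often lists whose members vary together are called wrongly. Alternatives were RLE (DESeq2-type) and upper-quartile scaling, no filter on low counts, robust shrinkage, leaving out mitochondrially encoded genes, DESeq2 1.42.0, limma-voom, a fit of only the groups compared, a replicate block, each week 8 batch as the only reference, week 13 libraries summed by their first number, a minimum fold change, and leaving out each replicate in turn. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.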

Results

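Polyadenylated RNA was sequenced from 13 libraries of human neural organoids, spherical cultures of neurons and glia called brain microphysiological systems, grown from the established induced pluripotent stem cell line NIBSC8. The libraries fall into 4 groups: week 8 of batch 1 (n = 3), week 8 of batch 2 (n = 3), week 12 of batch 2 (n = 3) and week 13 of batch 3 (n = 4). Total counts per library, in mega-counts (M), were 22.6 to 33.3 M in week 8 batch 1 and 23.2 to 32.5 M in week 8 batch 2. They were 23.6 to 29.7 M at week 12 and 23.5 to 29.6 M at week 13. The series title concerns the molecular parts needed for learning and memory, so a fixed panel of 20 genes of synapses, activity response and cell types was read in every comparison. Expression is given in CPM, counts scaled to a common library total, as mean ± SD, fold changes come from the model, and standard errors (SE) are on the log2 scale. Only batch 2 holds more than 1 age, and week 13 occurs only in batch 3, so age and batch cannot be told apart in any comparison that includes week 13. The labels do not say whether replicates are separate cultures, so p-values measure only the spread between these samples. Sample titles also carry codes that differ between the batches, and the labels do not explain them. Nor do they say what the first number of the week 13 replicates stands for. For each gene that spread was estimated over all 4 groups together, not within the groups compared. A group whose libraries differ more than the others can therefore have p-values that are too small.

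The 3 week 12 libraries were not alike. On the first principal component, which held 37.6% of the variance of log2 CPM, week 12 libraries 1 and 2 lay at 120.04 and 98.47. Library 3 lay at 26.56, and the other 10 libraries lay between -53.76 and -3.91. Pairwise correlations across genes, which are not independent, were 0.9492 to 0.9853 among the week 12 libraries and 0.9842 to 0.9882 within the other groups. Library 3 correlated more with the 4 week 13 libraries (0.9653 to 0.9698) than with week 12 libraries 1 and 2 (0.9492 and 0.9593). Library 3 also differed from libraries 1 and 2 in its share of counts from mitochondrially encoded genes, 8.57% against 4.92% and 5.41%, where week 13 libraries had 7.19% to 8.51%. For this reason values of each week 12 library are given beside the gene groups that they move with.

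**Figure D1:**
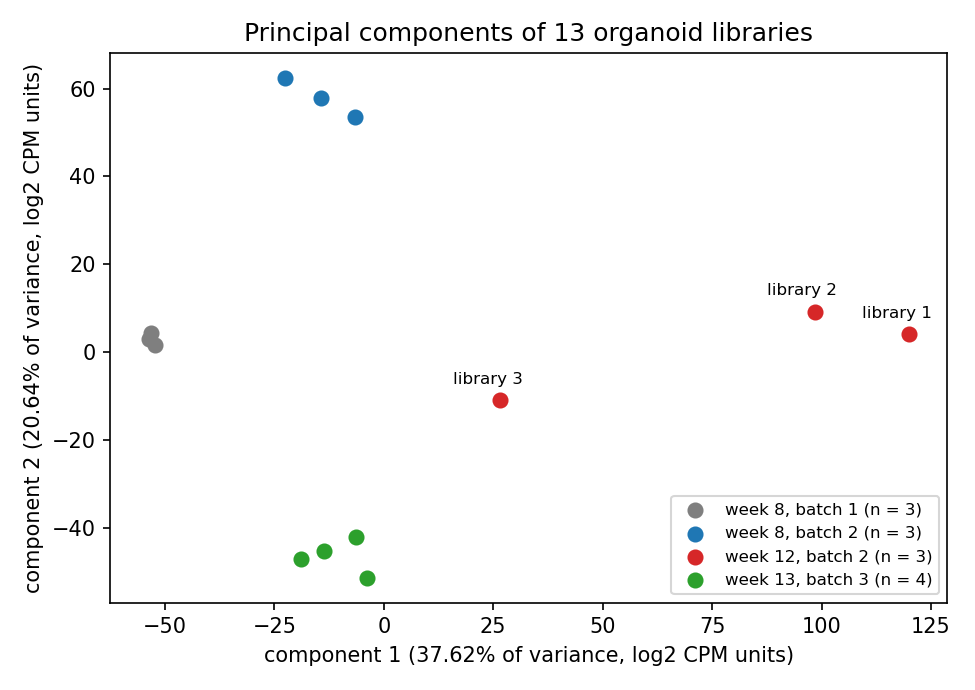
Principal components 1 and 2 of log2 CPM (axes in component units, with their share of variance) for 13 libraries coloured by group; each point is a library. Week 12 libraries 1 and 2 lie at 120.04 and 98.47 on component 1, library 3 at 26.56.

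The first question was how organoids of batch 2 differed between week 12 and week 8 (3 against 3 libraries). Genes of cell division were higher at week 12. The proliferation marker MKI67 (ENSG00000148773, chromosome 10, 128096659 to 128126385) rose 5.26-fold, from 26.8 ± 8.56 to 141 ± 32.4 CPM (SD, n = 3 each; SE 0.236, adjusted p = 1.12e-05). All 18 measured cell cycle genes rose (18 also adjusted over the list alone), with a median log2 fold change of 1.97. Among them were RRM2 (ENSG00000171848), a ribonucleotide reductase subunit (11.5-fold), and the replication factors PCNA (ENSG00000132646) (2.92-fold), MCM3 (ENSG00000112118) (2.97-fold) and MCM5 (ENSG00000100297) (3.03-fold). The list was called by camera with adjusted p = 7.19e-15, and had adjusted p = 0.441 with an estimated correlation. The rise was present in each week 12 library: the list medians relative to week 8 of batch 2 were 1.97, 1.70 and 1.98 in libraries 1, 2 and 3, against -0.20 to 0.43 in the other 10 libraries. The 13 cholesterol synthesis genes all fell (13 adjusted over the list alone; median -1.29, adjusted p = 4.38e-09, or adjusted p = 0.441 with an estimated correlation). These included HMGCS1 (ENSG00000112972) (2.44-fold lower), FDFT1 (ENSG00000079459) (2.68-fold) and DHCR7 (ENSG00000172893) (2.39-fold). The cholesterol list median was -1.49, -1.56 and -0.97 in week 12 libraries 1, 2 and 3.

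Glial markers moved apart from each other. GFAP (ENSG00000131095, chromosome 17, 44903161 to 44916937), an intermediate filament of astrocytes, rose 9.45-fold, from 253 ± 80.6 to 2387 ± 434 CPM (SD, n = 3 each; SE 0.232, adjusted p = 1.19e-06). The water channel AQP4 (ENSG00000171885) rose 8.70-fold and the calcium-binding protein S100B (ENSG00000160307) 1.89-fold, while ALDH1L1 (ENSG00000144908), a folate enzyme of astrocytes, fell 2.84-fold. Of 15 measured astrocyte markers 5 rose, 3 fell and 7 did not pass (5 and 3 adjusted over the list alone). The list was not called by camera or fry (camera adjusted p = 0.552), and its median of -0.02 and mean of 0.52 had opposite signs. Of 17 oligodendrocyte lineage markers 1 rose and 3 fell, the same counts adjusted over the list alone. CNP (ENSG00000173786), a myelin enzyme, rose (log2 change 0.59), and the precursor proteoglycan CSPG4 (ENSG00000173546) fell 1.77-fold. Neither the myelin gene MBP (ENSG00000197971) (11.2 ± 1.13 against 13.9 ± 0.934 CPM) nor the lineage factor OLIG2 (ENSG00000205927) (9.74 ± 9.01 against 13.7 ± 5.37 CPM) passed the test. The list was not called by camera or fry (median -0.32, mean 0.08, camera adjusted p = 0.364). Of 16 progenitor and radial glia markers 7 rose and 2 fell (8 and 2 adjusted over the list alone), among them the filament gene NES (ENSG00000132688) (3.71-fold), the matrix gene TNC (ENSG00000041982) (2.60-fold) and the lipid carrier FABP7 (ENSG00000164434) (1.46-fold). The progenitor list was not called by camera (adjusted p = 0.128) and was by fry (0.0322), and SOX2 (ENSG00000181449) was at 316 ± 10.2 and 323 ± 64.0 CPM. In week 12 libraries 1, 2 and 3 the medians were -0.19, -0.11 and 0.23 for astrocyte, -0.68, -0.62 and 0.12 for oligodendrocyte and 0.17, 0.13 and 0.44 for progenitor markers.

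The 8 genes that rose most by the fixed rule were all higher in week 12 libraries 1 and 2 than in library 3. A2M (ENSG00000175899, chromosome 12, 9067664 to 9116229), which encodes a secreted protease inhibitor, rose 78.6-fold (260 ± 182 against 3.32 ± 0.392 CPM; SE 0.635, adjusted p = 1.31e-05), with 364, 367 and 50.2 CPM in libraries 1, 2 and 3. ANXA1 (ENSG00000135046, chromosome 9, 73151757 to 73170393), a phospholipid-binding protein, rose 136-fold from 0.265 ± 0.146 CPM (SE 0.872, adjusted p = 5.58e-05), with 58.0, 44.0 and 5.87 CPM in the 3 libraries. SPOCD1 (ENSG00000134668) rose 60.3-fold, with 103.5, 83.7 and 2.67 CPM. The others that rose most were the transmembrane glycoprotein GPNMB (ENSG00000136235) (22.4-fold; 77.1, 69.8 and 5.66 CPM in libraries 1, 2 and 3) and the collagen COL14A1 (ENSG00000187955) (22.1-fold, with 22.8, 27.8 and 1.31 CPM). Next came the transcriptional repressor of the cell cycle E2F7 (ENSG00000165891) (18.5-fold, with 103, 93.2 and 11.9 CPM), the secreted glycoprotein CHI3L1 (ENSG00000133048) (16.4-fold, with 15.6, 16.3 and 1.97 CPM) and the caveolar protein CAV1 (ENSG00000105974) (14.5-fold, with 64.4, 57.1 and 11.3 CPM). Without libraries 1 and 2, an alternative chosen after seeing the data, the log2 changes of A2M, ANXA1, SPOCD1, GPNMB, COL14A1, E2F7, CHI3L1 and CAV1 were 3.92, 4.47, 1.34, 1.31, 0.74, 1.66, 1.52 and 1.88 in place of 6.30, 7.09, 5.92, 4.49, 4.46, 4.21, 4.04 and 3.86. The gene that fell most was FUT3 (ENSG00000171124, chromosome 19, 5842888 to 5851474), a fucosyltransferase (16.2-fold; 0.593 ± 0.117 against 9.78 ± 0.660 CPM; SE 0.264, adjusted p = 6.63e-07). ARHGAP8 (ENSG00000241484, chromosome 22, 44752558 to 44862788), whose locus overlaps PRR5, fell 11.8-fold (SE 0.175, adjusted p = 1.98e-07). The other 6 were ALS2CL (ENSG00000178038) (9.91-fold), the Rab exchange factor DENND1C (ENSG00000205744) (8.06-fold), the transcription factor TFAP2E (ENSG00000116819) (8.04-fold), the calcium release channel RYR1 (ENSG00000196218) (8.02-fold), the neurexin ligand NXPH3 (ENSG00000182575) (7.32-fold) and the unconventional myosin MYO15A (ENSG00000091536) (7.18-fold).

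Synaptic genes were lower at week 12 on average, in a pattern carried by libraries 1 and 2. Of 21 presynaptic genes 14 fell and 1 rose (14 and 1 adjusted over the list alone; median -0.79, adjusted p = 0.000588, or adjusted p = 0.703 with an estimated correlation). SYN3 (ENSG00000185666), a synapsin, fell 2.84-fold and the vesicle fusion protein VAMP2 (ENSG00000220205) 2.09-fold. The vesicle protein SYP (ENSG00000102003, chromosome X, 49187804 to 49200259) fell 1.89-fold (207.7 ± 140.5 against 392 ± 53.5 CPM; SE 0.33, adjusted p = 0.0367). It was at 110.0, 144 and 369 CPM in week 12 libraries 1, 2 and 3 and 334 to 439.8 CPM in week 8 of batch 2. Of 18 ionotropic glutamate receptor subunits 8 fell and none rose (8 adjusted over the list alone; median -0.73, adjusted p = 0.00434, or adjusted p = 0.703 with an estimated correlation), including GRIA2 (ENSG00000120251) (2.77-fold) and GRIN2D (ENSG00000105464) (2.38-fold). The obligatory NMDA receptor subunit GRIN1 (ENSG00000176884, chromosome 9, 137138390 to 137168762) was at 136 ± 139.7 against 314 ± 51.6 CPM and did not pass (adjusted p = 0.0713). Its levels were 36.4, 76.7 and 296 CPM in libraries 1, 2 and 3. Of 14 GABA receptor subunits 5 fell, among them GABBR1 (ENSG00000204681) (2.49-fold). Of 7 metabotropic glutamate receptors 4 fell, among them GRM4 (ENSG00000124493) (log2 change -1.44). The counts of both lists were the same adjusted over the list alone (medians -0.84 and -0.84, adjusted p = 0.00912 and 0.0246, or adjusted p = 0.703 for each with an estimated correlation). The metabotropic list was called in 9 of 12 alternatives (adjusted p 0.000452 to 0.877). Without week 12 library 1 camera did not call it (median -0.45, adjusted p = 0.0644). The per-library medians of week 12 libraries 1, 2 and 3 relative to week 8 of batch 2 were -1.48, -1.22 and -0.08 for presynaptic genes and -1.40, -0.88 and 0.01 for ionotropic glutamate receptors. They were -1.73, -1.30 and 0.03 for GABA receptors and -1.92, -1.38 and -0.19 for metabotropic receptors.

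Of 20 postsynaptic scaffold and adhesion genes 7 fell (3 adjusted over the list alone; median -0.34, adjusted p = 0.0226, or adjusted p = 0.703 with an estimated correlation). They included DLG4 (ENSG00000132535), the scaffold PSD-95 (1.84-fold), and the adhesion protein LRRTM2 (ENSG00000146006) (1.83-fold). Among 23 plasticity kinase and CREB signalling genes 6 fell and 3 rose (6 and 3 adjusted over the list alone; median -0.38, adjusted p = 0.0418, or adjusted p = 0.703 with an estimated correlation). The kinase CAMK2A (ENSG00000070808) fell 1.85-fold and the BDNF receptor NTRK2 (ENSG00000148053) 2.24-fold. Of 17 voltage-gated channel subunits 2 fell (2 adjusted over the list alone), and the list was called (median -0.65, adjusted p = 0.00576, or adjusted p = 0.703 with an estimated correlation). Of 10 immature neuron markers 5 fell (6 adjusted over the list alone; median -0.55, adjusted p = 0.0147, or adjusted p = 0.703 with an estimated correlation), including SOX4 (ENSG00000124766) (2.06-fold) and SOX11 (ENSG00000176887) (1.38-fold). The fry test did not call the postsynaptic, plasticity and channel lists (adjusted p = 0.0834, 0.054 and 0.061), which over 12 alternatives were called in 7 (4.35e-05 to 0.708), 6 (0.000595 to 0.877) and 9 (1.01e-06 to 0.703). The medians of week 12 libraries 1, 2 and 3 were -0.93, -0.54 and 0.08 for postsynaptic genes and -0.63, -0.67 and 0.05 for plasticity genes. They were -1.68, -1.0 and 0.15 for voltage-gated channels and -1.02, -0.91 and -0.06 for immature neuron markers. Among 17 immediate-early and activity-regulated genes 8 rose and 1 fell (8 and 1 adjusted over the list alone), but the list was not called by camera or fry (camera adjusted p = 0.204). The activity-induced transcription factors EGR1 (ENSG00000120738, chromosome 5, 138465490 to 138469315) and EGR2 (ENSG00000122877) rose 4.18-fold (SE 0.239, adjusted p = 3.7e-05) and 6.51-fold, the neuropeptide precursor VGF (ENSG00000128564) rose 2.91-fold, and the nuclear receptor NR4A1 (ENSG00000123358) fell 1.69-fold. FOS (ENSG00000170345) rose 1.81-fold (adjusted p = 0.0212), with 41.1, 38.8 and 17.3 CPM in libraries 1, 2 and 3. NPAS4 (ENSG00000174576), also activity-induced, rose 1.93-fold (adjusted p = 0.0493), and passed in 5 of 16 alternatives (0.0298 to 0.203). The median of the activity list was 0.78, 0.79 and -0.04 in libraries 1, 2 and 3. Panel genes that did not pass were the synaptic plasticity gene ARC (ENSG00000198576) (21.4 ± 7.27 against 14.96 ± 2.32 CPM) and the neurotrophin BDNF (ENSG00000176697) (3.35 ± 0.837 against 4.49 ± 0.834 CPM). The glutamate receptor genes GRIN2A (ENSG00000183454), GRIN2B (ENSG00000273079) and GRIA1 (ENSG00000155511), the scaffold gene HOMER1 (ENSG00000152413), the secreted synaptic protein gene NPTX2 (ENSG00000106236) and the transcription factor gene CREB1 (ENSG00000118260) did not pass either.

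Of 13 mitochondrially encoded genes 11 rose (11 adjusted over the list alone; median 0.83, adjusted p = 0.0011, or adjusted p = 0.703 with an estimated correlation). MT-ATP6 (ENSG00000198899) rose 2.17-fold, while MT-ND5 (ENSG00000198786), at 4341 ± 1896 against 3370 ± 196 CPM, did not pass. Their list medians were 0.46, 0.58 and 1.35 in week 12 libraries 1, 2 and 3. Of 20 ribosomal protein genes 16 fell (16 adjusted over the list alone; median -0.51, adjusted p = 1.5e-05, or adjusted p = 0.703 with an estimated correlation), such as RPL3 (ENSG00000100316) (1.82-fold) and RPL5 (ENSG00000122406) (1.77-fold). Their medians were -0.29, -0.65 and -0.59 in the 3 libraries. Those of week 8 batch 1 (-0.84 to -0.69) and week 13 (-0.71 to -0.48) also lay below week 8 of batch 2, the reference. Of 9 motile cilium and ependymal markers 6 rose (6 adjusted over the list alone; median 1.05, adjusted p = 0.00943, or adjusted p = 0.441 with an estimated correlation). The ciliary regulator FOXJ1 (ENSG00000129654) rose 2.32-fold, the dynein DNAH9 (ENSG00000007174) 7.49-fold and the central-pair protein HYDIN (ENSG00000157423) 2.20-fold. Of 11 interferon-response genes 6 rose (7 adjusted over the list alone; median 0.63, adjusted p = 0.0284, or adjusted p = 0.441 with an estimated correlation), among them IRF7 (ENSG00000185507) (2.30-fold) and ISG15 (ENSG00000187608) (1.69-fold). The interferon list was called in 9 of 12 alternatives (adjusted p 0.000393 to 0.441). Without week 8 library 2 camera did not call it (median 0.55, adjusted p = 0.0632). The medians of the cilium and interferon lists in libraries 1, 2 and 3 were 1.08, 0.77 and 1.09 and 0.69, 0.54 and 0.38. Of 10 p53 target genes 3 rose and 1 fell (3 and 1 adjusted over the list alone), with TP53I3 (ENSG00000115129) up 6.34-fold, and the list was not called by camera or fry (camera adjusted p = 0.437). Among 10 mature neuron markers 1 rose and 4 fell (1 and 4 adjusted over the list alone). The heavy neurofilament gene NEFH (ENSG00000100285) rose 4.37-fold, and the list was not called by camera or fry (camera adjusted p = 0.209). The medians in libraries 1, 2 and 3 were -1.27, -1.02 and 0.14 for mature neuron markers and 0.59, 0.28 and -0.42 for p53 targets. For unfolded-protein and integrated stress response genes, which neither camera nor fry called, they were 0.27, 0.05 and -0.87.

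In total 9079 of 19377 genes tested passed, 4759 higher and 4320 lower at week 12, and 3512 of them changed more than 2-fold (edgeR quasi-likelihood F test, Benjamini-Hochberg). Camera called 14 of 37 lists, 4 higher and 10 lower, and fry called 19. Of those only fry called, not yet named were the choroid plexus list, higher (adjusted p = 0.0439), and 6 lower lists: glutamatergic (0.0409), cholinergic and monoaminergic (0.0146), epithelial (2.3e-07), neural crest (0.000469), pluripotency (0.0322) and midbrain (0.0065). In week 12 libraries 1, 2 and 3 the medians were -1.36, -0.89 and 0.14 for glutamatergic and -1.40, -0.72 and 0.04 for cholinergic markers. They were -0.36, -0.20 and 0.02 for midbrain genes, so library 3 was not lower in these lists. All 3 libraries were lower for epithelial (-1.03, -0.85 and -1.43), neural crest (-0.43, -0.59 and -0.66) and pluripotency markers (-1, -0.69 and -0.24). The choroid plexus, pluripotency and midbrain lists had 3, 3 and 4 measured members. When only the 6 libraries of batch 2 were fitted the count was 4777 genes, and SYP, FOS and NPAS4 did not pass (adjusted p = 0.143, 0.0792 and 0.0994; over their alternatives 5.75e-07 to 0.713, 4.99e-05 to 0.883 and 0.0298 to 0.203). Nor did GRIN2D, GRM4 and ISG15 (0.0616, 0.0893 and 0.05; over their alternatives 7.2e-07 to 0.0813, 5.36e-07 to 0.0975 and 2.57e-05 to 0.417). Leaving out 1 library ended the call of SYP (week 8 or week 12 library 1 or 2; adjusted p 0.0767 to 0.135), FOS (week 8 library 2, week 12 library 1 or 2; 0.0839 to 0.0877) and GRM4 (week 12 library 2; 0.0577). Without week 12 library 3 GRIN1 (log2 change -2.50, adjusted p = 1.28e-06), GRIN2A (-0.76, 0.00503), GRIN2B (-0.92, 0.00125), GRIA1 (-0.30, 0.0467), BDNF (-0.68, 0.00256), ARC (0.75, 0.000364) and OLIG2 (-1.63, 0.000127) passed. Those were the lowest of their 16 alternatives, the highest being 0.757, 0.967, 0.659, 0.791, 0.837, 0.449 and 0.811. Camera then also called the mature neuron (0.00556), activity (0.0356), p53 (0.04), glutamatergic (0.0118) and cholinergic and monoaminergic lists (0.0319). There SYP, GRIA2, GRIN2D, GRM4, ALS2CL, NXPH3 and TFAP2E had log2 changes of -1.65, -2.17, -1.92, -2.38, -4.08, -4.03 and -4.34 in place of -0.92, -1.47, -1.25, -1.44, -3.31, -2.87 and -3.01. The medians of the GABA receptor, metabotropic receptor and channel lists were -1.57, -1.50 and -1.34. Without week 12 libraries 1 and 2, an alternative chosen after seeing the data that leaves 1 week 12 library, 6336 genes passed and 51.7% of the genes above passed in the same direction. There 8 lists were called, some of which were not called above, and the presynaptic, 3 receptor, immature neuron and interferon lists were no longer among them. COL14A1, GRM4, IRF7, ISG15, SYP and VGF no longer passed, the log2 change of FOS was -0.06, and the medians of the postsynaptic, plasticity and voltage-gated channel lists were 0.07, 0.04 and 0.15.

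**Figure D2:**
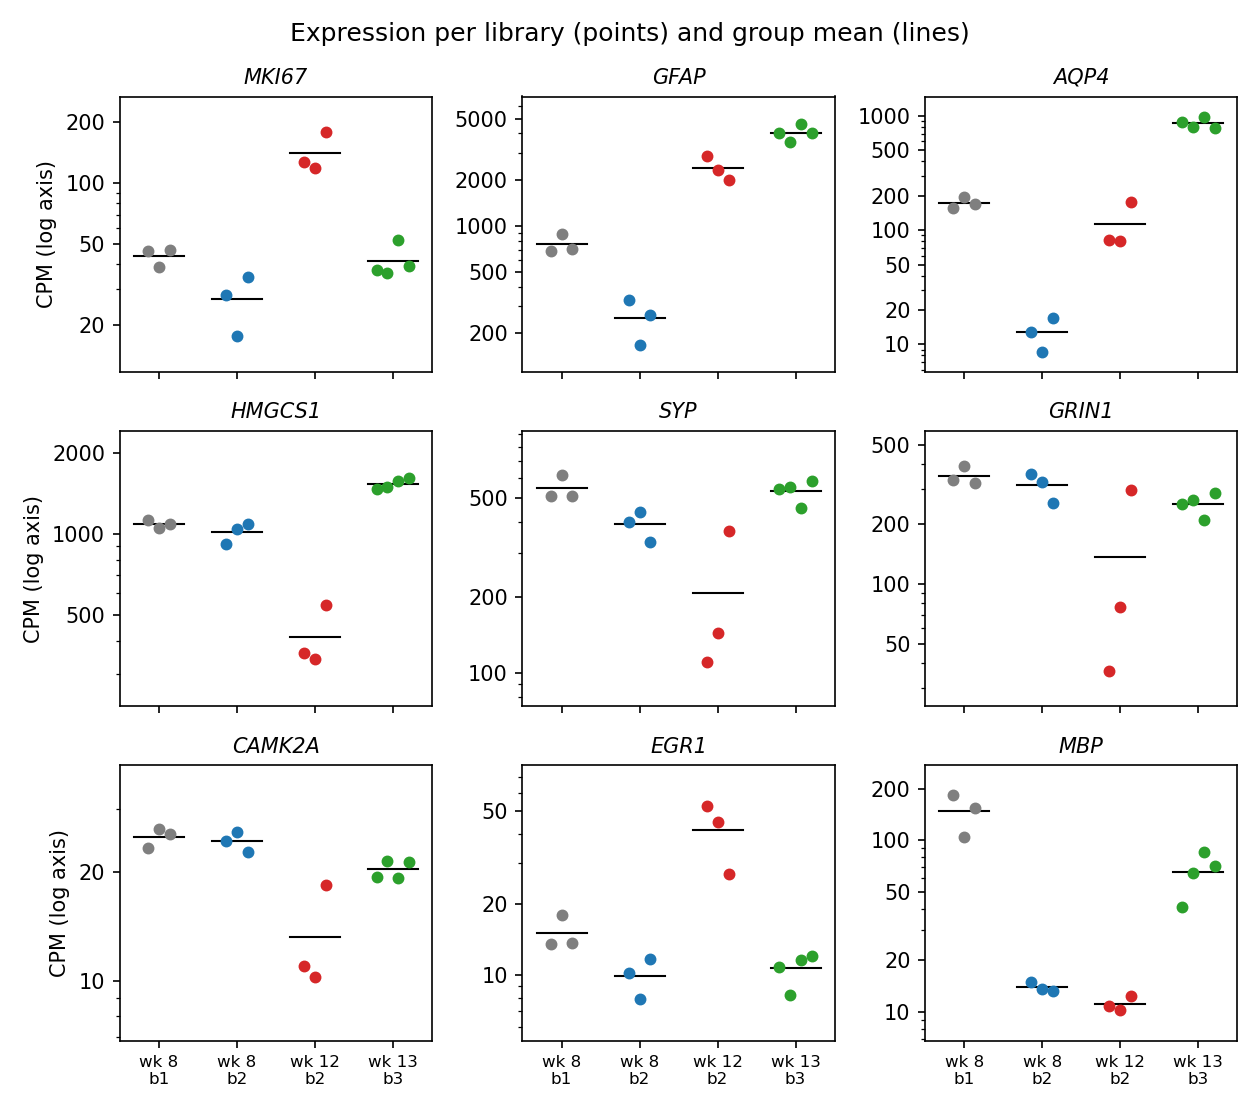
CPM (log axes) of 9 genes in each of 13 libraries (points) with group means (lines); wk is week and b is batch. MKI67 was at 141 ± 32.4 CPM at week 12 (n = 3), above every other group, while SYP and GRIN1 spread within week 12 from 110.0 to 369 and from 36.4 to 296 CPM.

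**Figure D3:**
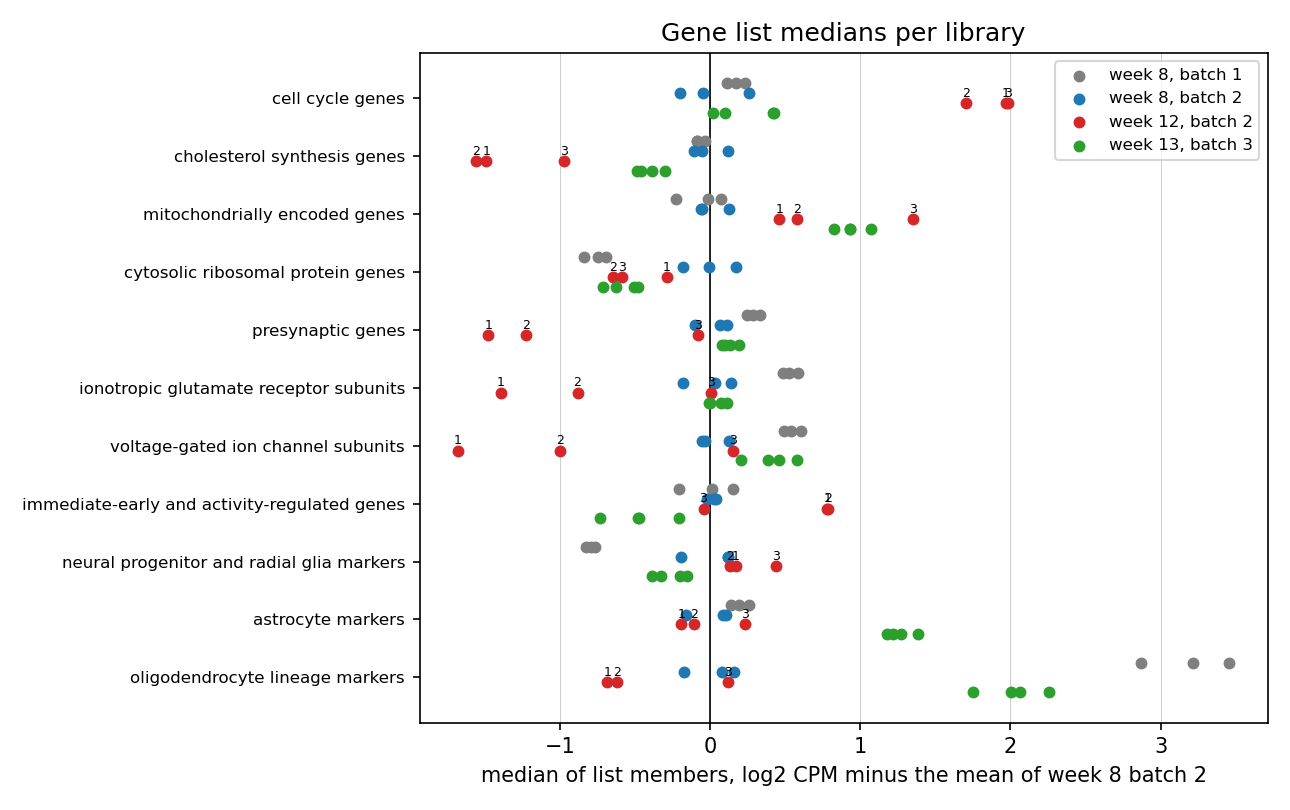
Medians of 11 fixed gene lists in each of 13 libraries, as log2 CPM minus the mean of week 8 batch 2; points are libraries coloured by group, and digits mark the week 12 libraries. Cell cycle medians were 1.97, 1.70 and 1.98 in week 12 libraries 1, 2 and 3, whereas presynaptic medians were -1.48, -1.22 and -0.08.

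The second question was how week 13 organoids of batch 3 (n = 4) differed from week 8 organoids, taken as the unweighted mean of batches 1 and 2 on the log scale (n = 3 each). Astrocyte genes were higher at week 13. GFAP rose 9.25-fold, to 4056 ± 456 CPM from 761 ± 109 in batch 1 and 253 ± 80.6 in batch 2 (SE 0.172, adjusted p = 8.1e-08). The water channel AQP4 (ENSG00000171885, chromosome 18, 26852038 to 26865818) rose 18.3-fold, to 867 ± 93.2 CPM from 174 ± 19.0 and 12.9 ± 4.30 (SE 0.236, adjusted p = 1.3e-07). The gap junction gene GJA1 (ENSG00000152661) rose 2.78-fold and S100B 2.53-fold, whereas the glycolytic enzyme gene ALDOC (ENSG00000109107) (202 ± 12.1 CPM at week 13) did not pass. Of 15 astrocyte markers 11 rose and 1 fell (11 and 1 adjusted over the list alone; median 1.17, adjusted p = 2.88e-06, or adjusted p = 0.733 with an estimated correlation). The largest rise by the fixed rule was that of AQP1 (ENSG00000240583, chromosome 7, 30911694 to 30925516), another water channel, also a choroid plexus marker, at 269.6 ± 48.4 against 5.44 ± 1.18 CPM (49.7-fold; SE 0.192, adjusted p = 3.4e-09). Of 3 measured choroid plexus markers AQP1 and the serotonin receptor HTR2C (ENSG00000147246) (2.79-fold) rose (2 adjusted over the list alone). The rest of the list had too few counts to be tested. Over all libraries TTR had 10 counts, KCNJ13 0, CLIC6 78, FOLR1 50, KL 54 and OTX2 4. A rise of these 3 markers therefore does not show that choroid plexus was present. That list was called by fry (adjusted p = 4.71e-06) and not by camera (0.0558), which called it against batch 1 alone (median 1.01, adjusted p = 0.0305, or adjusted p = 0.701 with an estimated correlation). The other genes that rose most were the secreted phospholipase PLA2G5 (ENSG00000127472, chromosome 1, 20028179 to 20091190) (32.3-fold), complement factor I, CFI (ENSG00000205403, chromosome 4, 109740694 to 109802179) (21.6-fold; 14.2 ± 1.08 CPM against 0.145 ± 0.144 in batch 1 and 2.86 ± 0.440 in batch 2), and the zinc transporter SLC39A12 (ENSG00000148482, chromosome 10, 17951839 to 18043292) (19.5-fold). Those that fell most were the procollagen protease ADAMTS2 (ENSG00000087116) (8.10-fold), the microfibril protein MFAP4 (ENSG00000166482) (7.56-fold) and DERL3 (ENSG00000099958), which acts in endoplasmic reticulum protein degradation (7.03-fold). Next came the transcription factor PAX8 (ENSG00000125618) (6.03-fold) and the clustered protocadherin PCDHGA11 (ENSG00000253873), which shares exons with its neighbours (5.92-fold). Some of these folds depended on the reference: the log2 changes against batch 1 and batch 2 alone were 6.55 and 2.31 for CFI, -4.23 and -1.81 for ADAMTS2, -3.96 and -1.22 for PAX8 and -4.15 and -0.98 for PCDHGA11.

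Camera called no neuronal list in this comparison, and fry called 2 lower. Among 10 mature neuron markers 3 rose and none fell (3 adjusted over the list alone; adjusted p = 0.402): the neurofilament genes NEFH (3.29-fold), NEFM (ENSG00000104722) (1.82-fold) and NEFL (ENSG00000277586) (1.57-fold). Of 21 presynaptic genes 1 rose and 1 fell (1 and 0 adjusted over the list alone; adjusted p = 0.9), and the release regulator CPLX1 (ENSG00000168993) rose 3.58-fold. Camera placed this list lower and fry higher. Of 10 immature neuron markers 4 fell and 1 rose (4 and 1 adjusted over the list alone; adjusted p = 0.177, and 0.0319 by fry), with SOX11 1.97-fold and SOX4 1.89-fold lower. Of 10 cholinergic and monoaminergic markers 4 fell, among them the dopamine synthesis enzyme TH (ENSG00000180176) (3.97-fold), and 1 rose (4 and 1 adjusted over the list alone; adjusted p = 0.293, and 0.0247 by fry). Against batch 1 alone camera called this list lower (median -2.02, adjusted p = 0.023, or adjusted p = 0.722 with an estimated correlation), and against batch 2 alone it did not (median -0.06, adjusted p = 0.891). Of the memory-related panel, BDNF rose 1.58-fold (7.45 ± 0.495 CPM against 4.91 ± 0.401 and 4.49 ± 0.834; SE 0.14, adjusted p = 0.00226). GRIA1 rose 1.62-fold and HOMER1 1.23-fold, ARC fell 1.81-fold (adjusted p = 0.00238) and DLG4 fell 1.39-fold (adjusted p = 0.0319). SYP, GRIN1, GRIN2A, GRIN2B, CAMK2A, CREB1, FOS, EGR1, NPAS4, NPTX2, MKI67 and OLIG2 did not pass. Some of these depended on the reference. Against batch 1 alone GRIN2A (log2 change -0.90, adjusted p = 0.0182) and GRIN2B (-0.78, 0.0385) passed. Against batch 2 alone GRIN2A (1.77, 0.00039), OLIG2 (1.27, 0.0316), MKI67 (0.62, 0.0336) and FOS (-0.80, 0.0235) did. Over 21 alternatives adjusted p ran from 0.00039 to 0.289 for GRIN2A, 0.0385 to 1 for GRIN2B, 0.0316 to 0.752 for OLIG2, 0.0336 to 0.778 for MKI67 and 0.0188 to 0.886 for FOS. Among 17 activity-regulated genes 2 rose and 7 fell (2 and 7 adjusted over the list alone), including NR4A1 (2.19-fold lower) and the phosphatase gene DUSP1 (ENSG00000120129) (1.93-fold lower), without a call of the list by camera (adjusted p = 0.165, and 0.0362 by fry).

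Of 13 mitochondrially encoded genes 12 rose (13 adjusted over the list alone; median 0.96, adjusted p = 2.1e-06, or adjusted p = 0.943 with an estimated correlation). MT-CO3 (ENSG00000198938) rose 2.26-fold, while MT-ND1 (ENSG00000198888) at 2070 ± 95.0 CPM did not pass. The share of counts from all genes of the mitochondrial genome, not only these 13, was 7.19% to 8.51% at week 13 and 3.49% to 4.98% at week 8. Of 12 unfolded-protein and integrated stress response genes 8 fell (9 adjusted over the list alone), including HERPUD1 (ENSG00000051108) (2.32-fold) and CHAC1 (ENSG00000128965) (1.75-fold), and the list was not called by camera (adjusted p = 0.0558, and 0.0484 by fry). Against batch 2 alone camera called it lower (median -0.80, adjusted p = 0.00681, or adjusted p = 0.905 with an estimated correlation), and against batch 1 alone it did not (median -0.42, adjusted p = 0.24). Of 10 p53 target genes 5 rose, TP53I3 by 4.44-fold, and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 0.101, and 0.0295 by fry). Against batch 1 alone camera called the p53 list higher (median 1.03, adjusted p = 0.000423, or adjusted p = 0.701 with an estimated correlation), and against batch 2 alone it did not (median 0.06, adjusted p = 0.891). Of 16 progenitor markers 4 rose, among them HOPX (ENSG00000171476) (3.95-fold; log2 changes of 2.65 and 1.31 against batch 1 and batch 2 alone), and 4 fell (4 and 4 adjusted over the list alone; adjusted p = 0.737). Camera called that list against batch 1 alone (median 0.23, adjusted p = 0.0178, or adjusted p = 0.722 with an estimated correlation) and not against batch 2 alone (median -0.27, adjusted p = 0.229). For oligodendrocyte lineage genes the answer depended on which week 8 batch was the reference. Against the mean of both batches 8 of 17 markers rose and none fell (8 adjusted over the list alone; median 0.67, adjusted p = 0.293). MBP was 1.45-fold higher (adjusted p = 0.0336; 65.5 ± 18.5 CPM against 148 ± 39.9 in batch 1 and 13.9 ± 0.934 in batch 2), and GPR17 (ENSG00000144230), a receptor of committed precursors, was 4.77-fold higher. Against batch 1 alone 8 fell and none rose (8 adjusted over the list alone), and the list was called lower (median -0.60, adjusted p = 0.00362, or adjusted p = 0.722 with an estimated correlation). Against batch 2 alone 14 rose and 1 fell (15 and 2 adjusted over the list alone), and the list was called higher (median 2.24, adjusted p = 1.73e-05, or adjusted p = 0.845 with an estimated correlation). The log2 changes were -1.17 for MBP and -0.26 for GPR17 against batch 1 alone, and 2.24 and 4.77 against batch 2 alone. Median, mean and test of a list differed in sign for motile cilium (median 0.16, mean -0.03), retinal (median -0.14, mean 0.21) and neural crest markers (median 0.04, mean 0.10, tested lower), none of which camera called, while fry called the neural crest list lower (adjusted p = 0.0362). The interferon list was called by fry (0.000499) and by camera against batch 1 alone (median 0.56, adjusted p = 0.00218, or adjusted p = 0.299 with an estimated correlation). The ribosomal list was called higher against batch 1 alone (median 0.22, adjusted p = 0.023, or adjusted p = 0.919 with an estimated correlation). It was called lower against batch 2 alone (median -0.58, adjusted p = 1.41e-06, or adjusted p = 0.845 with an estimated correlation).

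The test passed 7883 of 19377 genes, 3869 higher and 4014 lower, 1741 of them over 2-fold, and camera called 2 of 37 lists, the astrocyte and mitochondrially encoded genes, whereas fry called 12, among them also endothelial (adjusted p = 0.00398) and epithelial markers (0.000117). Against week 8 batch 1 alone HOMER1 and GRIA1 did not pass (adjusted p = 0.351 and 0.0734; over their alternatives 0.000854 to 0.351 and 5.09e-08 to 0.0734). Over its 21 alternatives DLG4 passed in 8 (adjusted p 3.28e-05 to 0.205), NEFL in 14 (1.85e-05 to 0.21) and MBP in 15 (1.71e-05 to 0.134). Summing week 13 libraries with the same first number, which leaves 2 samples, gave 4674 genes. Against week 8 batch 1 alone 9 lists were called and against batch 2 alone 5. In a fit of the 10 libraries alone with both week 8 batches pooled into 1 group, the labelled split called 4 lists. Of 100 splits fitted in that way 71 called at least as many, so the number of lists cannot be told from that of other splits.

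The third question was how week 13 (batch 3, n = 4) differed from week 12 (batch 2, n = 3), which are 1 week and also 1 batch apart. Oligodendrocyte lineage genes were higher at week 13. GPR17 (ENSG00000144230, chromosome 2, 127645864 to 127652639) rose 43.1-fold (33.0 ± 7.67 against 0.80 ± 1.01 CPM; SE 0.561, adjusted p = 1.81e-05). The lineage transcription factor SOX10 (ENSG00000100146, chromosome 22, 37970686 to 37987422) rose 18.7-fold (0.565, 0.407 and 5.62 CPM in week 12 libraries 1, 2 and 3 against 29.3 to 51.3 CPM at week 13), MBP 5.86-fold and OLIG2 3.43-fold. Of 17 such markers 12 rose and none fell (13 adjusted over the list alone; median 2.55, adjusted p = 2.67e-06, or adjusted p = 0.528 with an estimated correlation). All 18 cell cycle genes fell (18 adjusted over the list alone; median -1.82, adjusted p = 3.24e-13, or adjusted p = 0.528 with an estimated correlation), with MKI67 at 41.2 ± 7.57 against 141 ± 32.4 CPM (3.42-fold lower). All 13 cholesterol synthesis genes rose (13 adjusted over the list alone; median 0.99, adjusted p = 3.57e-07, or adjusted p = 0.528 with an estimated correlation). Of 15 astrocyte markers 12 rose and 2 fell (12 and 2 adjusted over the list alone; median 1.20, adjusted p = 3.62e-05, or adjusted p = 0.528 with an estimated correlation), including GFAP (1.70-fold). Synaptic genes were also higher. Of 21 presynaptic genes 15 rose (17 adjusted over the list alone; median 0.94, adjusted p = 5.03e-06, or adjusted p = 0.528 with an estimated correlation). Of 18 ionotropic glutamate receptor subunits 13 rose (13 adjusted over the list alone; median 0.96, adjusted p = 0.00011, or adjusted p = 0.528 with an estimated correlation). Of 14 GABA receptor subunits 13 rose and 1 fell (13 and 1 adjusted over the list alone; median 1.39, adjusted p = 6.39e-05, or adjusted p = 0.528 with an estimated correlation). SYP was 2.57-fold, GRIN2A 3.77-fold, GRIN2B 2.12-fold and GRIA1 2.24-fold higher. Among 17 activity-regulated genes 12 fell and 2 rose (12 and 2 adjusted over the list alone; median -1.42, adjusted p = 0.00308, or adjusted p = 0.528 with an estimated correlation). EGR1 fell 3.89-fold, FOS 3.15-fold and ARC 2.67-fold, while BDNF rose 2.23-fold. Presynaptic medians, relative to week 8 of batch 2, were -1.48, -1.22 and -0.08 in week 12 libraries 1, 2 and 3 and 0.08 to 0.19 at week 13. The activity medians were 0.78, 0.79 and -0.04 against -0.73 to -0.21.

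By the fixed rule the thyroid-hormone-responsive corepressor HR (ENSG00000168453) (19.1-fold), the neuropeptide NMB (ENSG00000197696) (14.3-fold) and C16orf89 (ENSG00000153446) (14.2-fold) were also among the genes that rose most. SPOCD1 (81.2-fold), the stress-inducible chaperone HSPA6 (ENSG00000173110) (41.5-fold), the receptor GPRC5A (ENSG00000013588) (38.9-fold), the hexokinase-like HKDC1 (ENSG00000156510) (27.3-fold) and E2F7 (20.1-fold) fell most. In week 12 libraries 1, 2 and 3 HSPA6 was at 18.1, 20.6 and 0.657 CPM, GPRC5A at 25.2, 24.9 and 0.903 and HKDC1 at 58.8, 57.9 and 6.93. CAMK2A rose 1.54-fold and HOMER1 1.31-fold, and GRIN1, DLG4, CREB1, NPAS4 and NPTX2 did not pass. The edgeR test passed 9892 of 19377 genes, 4521 higher and 5371 lower at week 13, 3250 of them over 2-fold. Camera called 18 of 37 lists, 13 higher and 5 lower, and fry 25. The others only fry called were GABAergic (adjusted p = 0.0121), endothelial (5.3e-05), neural crest (5.3e-05) and retinal markers (0.0383), higher, and interferon-response genes (0.00177), lower with a median of 0.00. In fits of the 7 libraries alone 13 of 35 splits gave at least the 17 lists of the labelled one, so the number of lists cannot be told from that of other splits. Week 12 libraries 1 and 2 carried much of this: without them 6207 genes passed, 47.9% of the genes above passed in the same direction, and the log2 change of DLG4 was -0.29 instead of 0.26. The log2 change of SOX10 was 2.84 without them and 6.44 without library 3, in place of 4.23, that of GPR17 4.08 and 7.32 in place of 5.43 and that of OLIG2 0.74 and 2.94 in place of 1.78. For SYP it was 0.55 and 2.13 in place of 1.36, for GRIN2A 1.16 and 2.57 in place of 1.91, for HR 3.31 and 5.14 in place of 4.26. Without library 3 GRIN1 (2.23, adjusted p = 2.01e-06), DLG4 (0.72, 3.59e-06) and CREB1 (0.22, 0.0267) passed, the lowest of 17 alternatives, whose highest were 0.415, 0.671 and 0.868. The ionotropic and GABA receptor medians were then 1.55 and 2.19. Without libraries 1 and 2 CAMK2A, GRIN2B, OLIG2, HSPA6 and GPRC5A no longer passed, and the presynaptic and ionotropic receptor lists were no longer called. In week 12 libraries 1, 2 and 3 the medians relative to week 8 of batch 2 were -0.68, -0.62 and 0.12 for oligodendrocyte lineage markers, against 1.75 to 2.25 at week 13. They were -0.19, -0.11 and 0.23 for astrocyte markers, against 1.18 to 1.39 at week 13. Median and mean differed in sign for 6 lists that camera did not call, of which fry called the mesenchymal (adjusted p = 0.0267) and epithelial lists (6.75e-06): glutamatergic (-0.07, 0.23), mesenchymal (-0.10, 0.04), epithelial (0.12, -0.04), pluripotency (-0.31, 0.09), HOX (-0.03, 0.35) and hypoxia genes (0.15, -0.06).

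The fourth question was how far 2 batches of the same labelled age differ, from week 8 of batch 2 against week 8 of batch 1 (3 against 3 libraries). Titles carry the code VC in batch 1 and LD in batch 2, with no meaning given, so these samples may differ in more than batch. Oligodendrocyte lineage genes were far lower in batch 2. MBP (ENSG00000197971, chromosome 18, 76978827 to 77133683) was at 13.9 ± 0.934 against 148 ± 39.9 CPM (fell 10.6-fold; SE 0.256, adjusted p = 1.83e-06). GPR17 fell 32.6-fold, the ventral neural tube and oligodendrocyte factor NKX2-2 (ENSG00000125820) 31.4-fold (log2 change -4.97, or -5.71 without batch 2 library 3) and OLIG2 3.90-fold. Of 17 oligodendrocyte lineage markers 15 fell and 1 rose (15 and 1 adjusted over the list alone; median -3.20, adjusted p = 3.79e-10, or adjusted p = 0.402 with an estimated correlation). All 20 ribosomal protein genes rose (20 adjusted over the list alone; median 0.78, adjusted p = 2.81e-12, or adjusted p = 0.402 with an estimated correlation). Of 16 progenitor markers 11 rose and 1 fell (11 and 2 adjusted over the list alone; median 0.82, adjusted p = 6.27e-05, or adjusted p = 0.402 with an estimated correlation), and of 11 interferon-response genes 6 rose and 1 fell (6 and 1 adjusted over the list alone; median 0.55, adjusted p = 0.042, or adjusted p = 0.402 with an estimated correlation). Of 10 p53 target genes 6 rose and none fell (7 adjusted over the list alone; median 1.01, adjusted p = 0.00106, or adjusted p = 0.465 with an estimated correlation), among them the secreted stress factor GDF15 (ENSG00000130513) (10.7-fold). Of 10 cholinergic and monoaminergic markers 7 fell and 1 rose (7 and 2 adjusted over the list alone; median -1.31, adjusted p = 0.0334, or adjusted p = 0.6 with an estimated correlation). Of 18 ionotropic glutamate receptor subunits 8 fell and 1 rose (8 and 1 adjusted over the list alone; median -0.55, adjusted p = 0.0469, or adjusted p = 0.868 with an estimated correlation). GRIN2A fell 6.37-fold, GRIN2B 2.74-fold and GRIA1 1.64-fold. Of 9 motile cilium markers 4 fell and 1 rose (5 and 1 adjusted over the list alone; median -0.76, adjusted p = 0.0469, or adjusted p = 0.464 with an estimated correlation). Over 10 alternatives the ionotropic receptor list was called in 4 (adjusted p 0.0254 to 0.868), the cilium list in 6 (0.000743 to 0.464), the cholinergic and monoaminergic list in 7 (0.00386 to 0.6) and the interferon list in 8 (0.000182 to 0.402).

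The splicing factor of neurons RBFOX1 (ENSG00000078328, chromosome 16, 5239802 to 7713338) fell 31.7-fold (4.16 ± 0.640 against 131 ± 1.40 CPM; SE 0.188, adjusted p = 5.82e-09), and by the fixed rule the imprinted gene NNAT (ENSG00000053438, chromosome 20, 37521206 to 37523693) 44.2-fold and LRRC61 (ENSG00000127399) 41.0-fold. The vasodilator peptide ADM (ENSG00000148926, chromosome 11, 10304680 to 10307397), a gene induced by low oxygen, rose 21.5-fold, the clustered protocadherin PCDHA5 (ENSG00000204965) 10.1-fold, the homeobox gene HOXD8 (ENSG00000175879) 9.55-fold and the monooxygenase MOXD1 (ENSG00000079931) 9.22-fold. GFAP fell 3.01-fold, MKI67 1.64-fold and HOMER1 1.27-fold. Levels of ARC, BDNF, CAMK2A, CREB1, DLG4, EGR1, FOS, GRIN1, NPAS4, NPTX2 and SYP did not pass the test. The edgeR test passed 5960 of 19377 genes, 2920 higher and 3040 lower in batch 2, 2047 of them over 2-fold, with no difference in labelled age. Camera called 8 of 37 lists and fry 14. Fry did not call the ionotropic receptor list (adjusted p = 0.172) and alone called astrocyte (0.0168) and neural crest markers (0.000182), lower, and 5 lists that were higher. These were mesenchymal (0.00712), epithelial (2.06e-07), pluripotency (8.7e-06), midbrain (3.21e-06) and hindbrain and HOX genes (0.00227). Immature neuron markers, called by neither, had a median of -0.05 and a mean of 0.10. Of 15 alternatives HOMER1 passed in 9 (adjusted p 0.0128 to 0.103), MKI67 in 11 (0.0019 to 0.118) and GDF15 in 14 (1.23e-08 to 0.0625). Among genes that did not pass above, FOS passed in 4 (0.00167 to 0.175). DLG4, EGR1 and SYP passed in 2 each (0.0123 to 0.436, 0.014 to 0.25 and 0.00331 to 0.527).

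The last question was which differences between a later and an earlier week recurred in libraries that share no control. Week 12 against week 8 within batch 2 was set beside week 13 of batch 3 against week 8 of batch 1, where 6229 genes passed. In the second of these age and batch cannot be told apart. A2M (log2 fold changes of 6.30 and 3.88), CFI (2.99 and 6.55), PLA2G5 (2.65 and 5.00), GFAP (3.24 and 2.41), AQP4 (3.12 and 2.32) and the p53 target TP53I3 (ENSG00000115129, chromosome 2, 24077433 to 24085861) (2.67 and 2.16) were higher in both. RYR1 (ENSG00000196218, chromosome 19, 38433699 to 38587564) (-3.00 and -2.18) and MYO15A (ENSG00000091536, chromosome 17, 18108706 to 18179806) (-2.84 and -1.68) were lower in both. These genes are among those named above and are not a ranking of shared changes. RPE65 (3.13 and 3.12) and S100A11 (3.024 and 5.385) were also higher in both, and SCUBE1 (-2.30 and -2.06) and SLC7A3 (-2.22 and -2.03) lower. Of 3134 genes that passed in both comparisons, 73.8% changed in the same direction. There were 1189 genes higher in both (738.5 expected of independent lists, a ratio of 1.61) and 1124 lower in both (718.3 expected, 1.56). In opposite directions 425 and 396 changed (791.3 and 670.4 expected). Across genes, which are not independent, log2 fold changes correlated with Pearson r = 0.234 and a Spearman coefficient of 0.259. With no filter on low counts and with DESeq2, r was 0.102 and 0.148, and the ratio of genes changed alike to those expected was 2.84 and 2.85 in place of 1.59. Both fits held 36257 genes in place of 19377, which by itself lowers the number expected (653.1 and 851.9 in place of 1457). With an added minimum of 1 for the absolute log2 fold change 509 genes were shared (160.1 expected, 3.18), and without week 12 replicate 3 the number shared was 4048 (ratio 1.5).

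**Figure D4:**
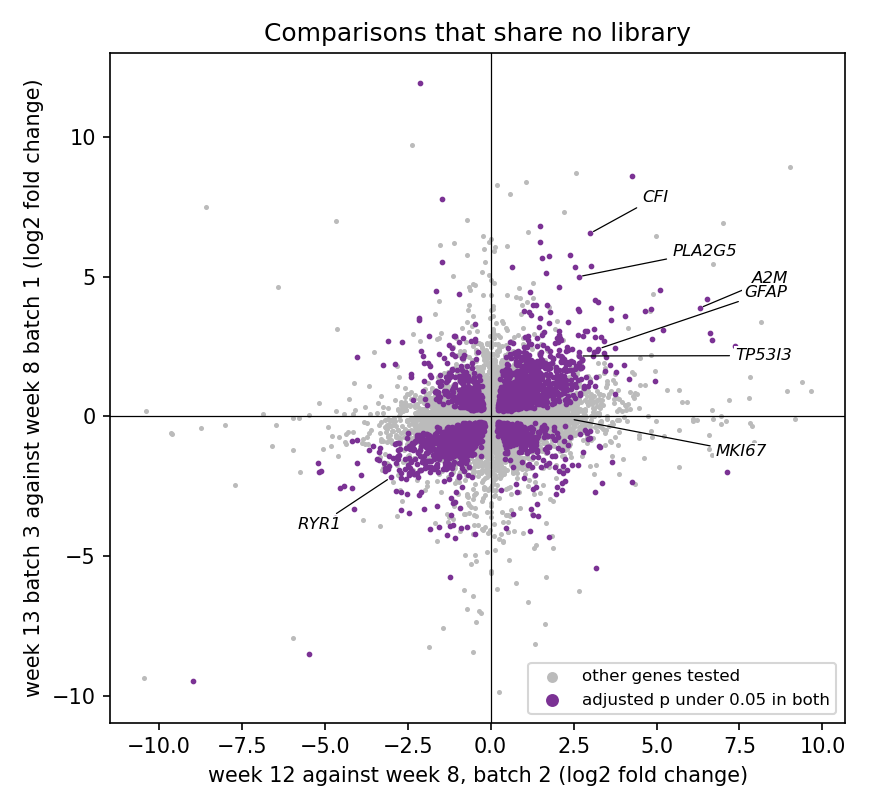
Log2 fold change of week 12 against week 8 in batch 2 (x) and of week 13 batch 3 against week 8 batch 1 (y) for 19377 genes; coloured points passed in both comparisons, and grey points are the other genes tested. Of the 3134 coloured genes 73.8% lie in the quadrants of equal sign, among them A2M at 6.30 and 3.88.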

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

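The tests of the 3 patterns weighed here were chosen after the results were seen, and the counts of other splits were chosen before, except those of lists in the last 2 contrasts.

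In week 13, 4 of 62 values tested had a library far from the other 3 by Dixon's ratio, and chance alone does this in about 1 in 20 groups. CREB1 was at 43.6 CPM in library 1-1 against 42.3 to 42.5 in the others. OLIG2 was at 40.1 CPM in library 2-1 against 30.6 to 31.1, and MKI67 at 52.5 CPM in the same library against 36.2 to 39.0. The median of unfolded-protein and integrated stress response genes was -0.62 in library 2-2 against -0.81 to -0.80.

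The change from week 8 to week 12 in batch 2 differed from the change from week 8 of batch 1 to week 13 of batch 3, by a test of the difference itself, for 6316 genes (edgeR, adjusted p under 0.05). Among 20 panel genes 5 differed, with log2 differences of 1.33 for ARC, 2.56 for EGR1, -1.03 for BDNF, 0.83 for GFAP and 2.48 for MKI67. Among the lists 10 differed by camera, with median differences of 1.80 for cell cycle, 1.28 for motile cilium, 0.98 for activity-regulated, -0.56 for presynaptic, -0.72 for GABA receptor, -0.64 for voltage-gated channel, -0.48 for astrocyte, -0.70 for hindbrain and HOX (medians of -0.29 in the first and 0.51 in the second change), -1.18 for cholesterol synthesis and -0.75 for ribosomal protein genes. With an estimated correlation 0 of 37 lists passed by camera (2 had an unadjusted p under 0.05), and fry called 12. Age at the later time point and batch both differ between these changes and cannot be told apart.

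The first pattern weighed is that week 12 libraries 1 and 2 lay far below library 3 in neuronal genes. Depth is argued against, since the total of library 3 (24.97 M) lay between those of libraries 1 and 2 (23.62 and 29.74 M). Thinning all libraries to the smallest total was a weak test, as totals were already alike. After it the presynaptic median of library 3 still lay 1.17 above the nearer of the pair (1.15 before). A label exchanged with another group is argued against, since the lowest week 12 library lay 1.28 above all 10 other libraries in cell cycle genes. Library 3 did correlate more with week 13 (0.9653 to 0.9698) than with libraries 1 and 2 (0.9492 and 0.9593), yet less than week 13 libraries did with each other (0.9859 to 0.9881), and its mitochondrial share of 8.57% lay near theirs (7.19% to 8.51%). Loss of neurons alone, raising every other cell type alike, is argued against, since the oligodendrocyte median of the higher of the pair lay -0.742 from that of library 3 (week 8 batch 2 libraries spanned 0.334). Differences between cultures in cell composition or state, or in handling, may remain and were not tested.

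The next pattern is the lower oligodendrocyte lineage genes in week 8 of batch 2. With RLE and upper-quartile scaling the list median was -3.18 and -3.23, against -3.20. Loss of these cells alone, raising every other type alike, is argued against, as progenitor and mature neuron medians moved 1.23 apart (largest range of either list within a week 8 group 0.307). A difference between batches in when or how much of this lineage forms is a hypothesis that may account for it, and cannot be told apart from other differences between the batches.

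The last pattern is the rise of cell cycle genes in all 3 week 12 libraries. Loss of neurons raising all other types alike is argued against, as the cell cycle median lay at least 1.54 above the progenitor median in each library. Depth is argued against, as week 12 totals (23.6 to 29.7 M) lay within those of week 8 batch 1 (22.6 to 33.3 M). Thinning to the smallest total was again a weak test. After it the lowest week 12 library still lay 1.23 above the highest other (1.28 before). A larger share of dividing cells at week 12 in this batch may be present as a hypothesis, and with 1 batch at week 12 age was not separated from other differences between these cultures.

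Other splits of the same libraries were fitted on those libraries alone with edgeR, as 2 groups. For week 13 against week 8 this pools the week 8 batches, so that the labelled split is not the contrast reported above. For week 12 against week 8 the labelled split gave 4777 genes and the highest other 0, and 14 lists against 19 in the highest other (4 of 10 splits gave as many lists, and 1 of 10 as many genes). For the week 8 batches the labelled split gave 8102 genes and the highest other 0 (1 of 10), and 16 lists against 15 (1 of 10). In both designs 10 splits are too few for a share under 0.05. For week 13 against week 8 the labelled split gave 6721 genes and the highest of 100 splits 3915, a split that grouped week 8 batch 1 library 2 with the 3 batch 2 libraries, so chance was excluded for genes (1 of 100) as far as the grouping of single libraries goes. It was not excluded for lists, where 71 of 100 splits gave at least the 4 lists of the labelled split (highest 17). For week 13 against week 12 it was excluded for genes in the same sense, with 7993 against 0 (1 of 35), and not for lists, where 13 of 35 splits gave at least the 17 lists of the labelled split (highest 21). For genes shared by the independent comparisons the labelled splits gave 1949 and the highest other 0, but in each of the 99 other pairs of splits a comparison called no gene, so this count tests nothing. These splits move single libraries, and with week 13 in 1 batch they do not exclude a chance difference between batches.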

How the results depend on the processing

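The alternative without week 12 libraries 1 and 2, and all alternatives for lists in the last 2 contrasts, were chosen after seeing the data. Counts of genes stayed within 1.5 times in 8 of 10 alternatives for week 12 against week 8, 10 of 11 for week 13 against week 8, 9 of 10 for week 13 against week 12, 9 of 9 for the week 8 batches and 5 of 6 for shared changes. Of 3153 values of named genes under alternatives 3015 kept their side of the threshold, 96 lost the call, 36 gained one and 6 reversed. A change of sign counted as reversed only where the gene passed in either fit. Genes that passed in neither may have changed sign among the 3015. At these depths and group sizes 27 to 47 of 100 genes with a 1.5-fold change and 76 to 88 with a 2-fold change were recovered on simulated data.

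Week 12 against week 8 gave 4777 genes with only the 6 libraries. Such fits also gave fewer genes for week 13 against week 12 (7993 in place of 9892). They gave more for week 13 against week 8 (10563 in place of 7883) and the week 8 batches (8102 in place of 5960). The count thus fell only in contrasts with week 12, whose libraries were least alike (correlations 0.9492 to 0.9853). The fit of all 13 libraries shares 1 estimate of spread, to which the closer libraries of the other groups contribute. For week 12 against week 8 a replicate block gave 2011, although the numbers do not pair libraries, and ended the call of 23 of 75 named genes: CAMK2A, CNP, COL14A1, CSPG4, DLG4, FABP7, FOS, GABBR1, GRIA2, GRIN2D, GRM4, IRF7, ISG15, LRRTM2, MT-ATP6, NPAS4, NR4A1, RPL5, SOX11, SPOCD1, SYP, VAMP2 and VGF. Week 13 against week 8 gave 4674 with summed libraries, which are fewer samples. Shared genes numbered 509 with a minimum log2 fold change of 1, which removes genes by construction. With no filter on low counts and with DESeq2 the ratio of shared genes to those expected was 2.84 and 2.85 and r was 0.102 and 0.148, against 1.59 and 0.234. The number expected is divided by the genes in the fit, 36257 in both in place of 19377. It was 653.1 and 851.9 against 1457, while 1858 and 2430 genes were shared against 2313. The higher ratio is therefore no sign of closer agreement. Why r was lower was not tested. With an estimated correlation 0 lists were called in each contrast, 14 and 2 before in the first 2. In week 13 against week 8, fry called 12 lists, and 9 and 5 were called with week 8 batch 1 or batch 2 alone as reference; the cause was not tested. Without week 12 libraries 1 and 2, 8 lists were called in week 12 against week 8 and 6207 genes in week 13 against week 12, with the lone week 12 sample assumed to vary like the other groups.

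Leaving out 1 library gave 7164 to 12267 genes for week 12 against week 8, 6407 to 7336 for week 13 against week 8, 7763 to 12560 for week 13 against week 12, 4006 to 4879 for the week 8 batches and 1570 to 4048 shared genes, the last without week 12 library 3. Lists numbered 12 to 19, 2 to 4, 14 to 20 and 4 to 10. The 4 lists of week 13 against week 8 came without week 8 batch 1 library 1 or week 13 library 2-1. The 4 and 5 lists of the week 8 batches came without library 2 of batch 1 or of batch 2.

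With week 8 batch 1 alone as reference, log2 changes at week 13 reversed to -0.26 for GPR17, -0.90 for GRIN2A and -1.17 for MBP, and medians to -0.60 for oligodendrocyte and 0.22 for ribosomal genes. Without week 12 libraries 1 and 2, values against week 8 reversed to -0.056 for FOS, 0.624 for GRIN2A, and medians of 0.074, 0.036 and 0.147 for postsynaptic, plasticity and voltage-gated channel genes. Against week 13 they reversed to -0.29 for DLG4 and, by the test or the median, to 0.086 for postsynaptic and -0.33 for mitochondrially encoded genes.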

Other observations

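All genes below were chosen after their values were seen, and no test of an explanation was run on them.

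Most genes of the anterior brain that were looked up had few or no counts, and hindbrain genes of the HOX family were present in every group. Over all 13 libraries SIX3, a forebrain factor, had 5 counts, OTX2 4, OTX1 6 and TBR1 58, and EMX1, NKX2-1 and SIX6 had 0, which for each library allows up to 3 counts. LHX2, also a forebrain gene, had group means of 2.65 to 6.39 CPM. HOXB3, expressed in the hindbrain and spinal cord, was at 49.99 ± 3.35 CPM (SD, n = 3) in week 8 batch 1, 80.4 ± 5.72 (n = 3) in week 8 batch 2, 49.5 ± 17.9 (n = 3) at week 12 and 58.1 ± 3.35 (n = 4) at week 13. The serotonergic genes TPH2, an enzyme of serotonin synthesis (9.95 ± 3.86 against 4.13 ± 0.474 CPM, n = 3 each, edgeR adjusted p = 0.00108) and SLC6A4 (4.08 ± 2.91 against 0.0768 CPM, adjusted p = 9.56e-05) were higher in week 8 of batch 1 than of batch 2. The midbrain-hindbrain boundary genes EN1 (17.7 against 5.43 CPM) and PAX5 (20.6 against 3.74 CPM) had higher means in batch 2.

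Microglial genes were at or near 0 over all libraries, with 2 counts of PTPRC, 14 of AIF1 and 0 of TYROBP, C1QB, C1QC and TREM2. CD68, a lysosomal protein gene, was the exception in that list, at 31.5, 23.2 and 0.698 CPM in week 12 libraries 1, 2 and 3. Other genes split these libraries in the same way: the stress cytokine GDF15 was at 276, 278 and 7.67 CPM, the hyaluronan receptor CD44 at 167, 152.5 and 20.4, and the cell cycle inhibitor CDKN1A at 691, 557 and 162, while the oligodendrocyte factors OLIG1 (1.66, 2.07 and 29.1 CPM) and SOX10 (0.565, 0.407 and 5.62 CPM) went the other way. The choroid plexus gene TTR had 10 counts over all libraries and KCNJ13 had 0, the pluripotency genes NANOG and POU5F1 had 4 and 14. The fibrillar collagen gene COL1A2 was at 16.9 CPM in week 13 library 1-1, 3.41 in week 8 batch 2 library 2 and 2.02 in week 12 library 1.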
